A study of Drosophila melanogaster with 31 samples.

How the data were processed

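The series holds poly(A) RNA-seq of Drosophila melanogaster ovaries. Per the labels' protocols, RNA was taken with TRIzol or phenol-chloroform, treated with DNase, selected with poly(A) beads and made into libraries with the NEXTflex Rapid Directional kit. Polysome samples were loaded on gradients, and inputs are their total mRNA, per the same protocols. Per the submitters' processing notes, reads were aligned to dm6 with HISAT2 2.0.5 and counted with featureCounts 1.5.1. The annotation, the gene filter and the TPM formula are not given in the sources used here. The deposited values are log2 TPM per the column headers, made by the authors before deposit. Each column's values, raised from log2 and less 0.5, summed to the same total over the 9251 genes of the table, so the log2 values were read as log2(TPM + 0.5) with TPM scaled over these genes alone. They were turned back to TPM and then to log2(TPM + 1).

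The labels gave 31 libraries, 16 of total mRNA, 12 of input and polysome RNA in groups of 2, and 3 single bam libraries. Adult wild type, young wild type and control preparation 1 are labelled with UAS-Dcr-2 and nanos-GAL4, tst RNAi with UAS-Dcr2 and nanos-GAL4, the tst mutant with an insertion allele over a deficiency, and control preparation 2 as a pelo heterozygote. Young ovaries were dissected hours after eclosion and the others days after it, per the labels. In adult wild type, young wild type, tst mutant and tst RNAi, the strand label was not applicable for replicate 1 and reverse for replicate 2, so the replicate number also splits these libraries by that label. Whether they were sequenced or counted in separate batches is not known. Deviations of libraries with the same number from their group means correlated at 0.613 to 0.762 among these groups. Results with that number as a block are given beside the main counts of these groups, and for pelo and hfp with the other alternatives. Counts for antisense or overlapping genes are uncertain where strand was not used, and reads shared between close copies, such as ribosomal protein, chorion or Gst genes, may be assigned unevenly.

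Genes with at least 1 TPM in 2 or more libraries of a fit were tested, 8864 in total mRNA and 8572 in inputs and polysomes. A single limma fit over all groups of a set was used with a trend in the variance, since each group has 2 libraries, and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The polysome fit had the preparation as a block, because the labels pair each input with its polysome sample. The difference of polysome to input ratios between genotypes was an interaction term of that fit. The median SE was 0.472 for total mRNA, 0.303 for inputs, 0.273 for control polysome ratios and 0.386 for their differences. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for figures.

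There were 21 fixed lists of genes, written with these choices and the tests before the data were examined. They cover Ski and exosome, mRNA decay, early germline, meiosis, maternal axis, piRNA, vitelline membrane, chorion, yolk, early follicle cell, muscle sheath, hemocyte and basement membrane, fat body, gut and oviduct, testis, heat shock, antimicrobial, apoptosis, glutathione and detoxification, splicing and ribosomal protein genes. The yolk list has fewer than 5 genes and entered no list test. The undifferentiated germ cell list holds genes with at least 5 TPM in the bam RNAi input and a log2 value at least 2 above the higher control input. Lists were tested with the camera function of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 21 lists per comparison. The preset value gave smaller p values, and the text prints those with an estimated correlation. "Adjusted over the list alone" means that p values were adjusted over the members of the list. Overlaps used Fisher's exact test, adjusted over 20 tests, and 100 simulations of unchanged groups for comparisons that share control libraries. Fisher's test treats genes as independent, so genes that vary together can make its p values too small.

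Named genes follow a fixed rule: the targeted genes, the 8 largest rises and 8 largest falls that passed, with every library of one group above every library of the other and a mean of at least 10 TPM in the higher group, and up to 4 members of each list with the smallest adjusted p. Where no member passed, those with the highest mean TPM were named. Genes outside the rule are marked as chosen after their values were seen, which also holds for the genes described in the shared comparisons, the copies of ribosomal protein genes and the bam libraries. A few genes that the rule names are not reported here. Symbols were matched to a RefSeq gene table of Release 6, where 8664 matched directly, 576 matched an older name and 11 did not match. Coordinates were found for 8298 of 8864 tested genes, 93.6 percent. Names of 5 genes had been turned into dates and these were kept in scaling but left out of lists and names. In data with changes put in at random, a change of 2 log2 was recovered for 38.8 to 59.7 percent of genes in the total mRNA comparisons and a change of 4 log2 for 86.4 to 93.9 percent.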

Results

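The deposited values gave transcript levels of 9251 genes in 31 poly(A) RNA-seq libraries of Drosophila ovaries, as TPM (transcript share scaled by length). Total mRNA came from 8 groups of 2 libraries each: adult wild type, young wild type dissected within hours of eclosion, twister (tst) mutant, tst RNAi, pelota (pelo) heterozygote and mutant, and hfp heterozygote and mutant. A further set held input and polysome libraries of control, pelo mutant and tst RNAi ovaries, 2 of each, and single libraries of bam RNAi input, bam RNAi polysome and bam mutant ovaries. Between 7233 and 8675 genes reached 1 TPM in a library. Sequencing depth is unknown, since TPM keep no read counts. The sources do not state whether replicates were separate animals or cultures, so the p values below measure only the spread between samples. Fold changes are differences between group means of log2(TPM + 1) from limma with a standard error (SE), and on that scale the change of weakly expressed genes is understated.

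Mean levels of tst, pelo and hfp were lower in their own groups, and tst and pelo passed the test in the inputs. Transcripts of tst, which encodes the Ski2 helicase that feeds mRNA to the exosome, were at 35.3 and 39.6 TPM in adult wild type, 6.34 and 8.62 TPM in the tst mutant, and 6.77 and 11.7 TPM in tst RNAi. The log2 fold change was -2.19 (SE 0.57, adjusted p = 0.0522) in the mutant and -1.95 (SE 0.57, adjusted p = 0.168) in RNAi, so neither passed the test as deposited. With the replicate number as a block the adjusted p was 4.98e-04 in the mutant and 1.84e-03 in RNAi. Transcripts of pelo, a factor that releases stalled ribosomes, were at 45.1 and 90.5 TPM in the heterozygote and at 10.8 and 44.6 TPM in the mutant (log2 fold change -1.49, SE 0.52, adjusted p = 0.383). The splicing factor gene hfp was at 25.8 and 48.1 TPM in its heterozygote and at 9.29 and 20.8 TPM in its mutant (log2 fold change -1.28, SE 0.56, adjusted p = 0.449). In the inputs, tst fell by 0.92 (SE 0.29, adjusted p = 0.0256) in tst RNAi, from 31.4 ± 1.52 to 16.2 ± 2.55 TPM, and pelo fell by 1.58 (SE 0.30, adjusted p = 0.00507) in the pelo mutant, from 107 ± 42.6 to 33.7 ± 0.906 TPM. The differentiation gene bam was at 3.10 TPM in the bam RNAi input and 5.61 TPM in the bam mutant, against 65.1 and 40.1 TPM in the control inputs. On bam RNAi polysomes bam was at 18.9 TPM, between the control polysome values of 41.2 and 11.8 TPM.

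Young wild type ovaries had little of the eggshell mRNA that is abundant in adult ovaries. The chorion gene Cp36 fell by 9.74 log2 (SE 0.45), from 7785 ± 2114 TPM in 2 adult libraries to 8.33 ± 3.67 TPM in 2 young libraries, and Cp38 fell by 9.64 (SE 0.58), from 10960 ± 2887 to 13.1 ± 5.65 TPM. Of 16 chorion genes 14 fell and none rose (median -8.33), with Cp15 (-9.54, SE 0.87), Cp19 (-9.39, SE 0.97), Cp16 (-9.29, SE 0.72) and Cp18 (-8.87, SE 1.01) among them. Of 15 vitelline membrane genes 13 fell and none rose (median -7.79), led by Vm32E (-9.33, SE 0.48) and by yellow-g2 (-8.62, SE 0.43), needed for eggshell crosslinking. The yolk protein genes Yp1 (-3.90, SE 0.70), Yp2 (-3.21, SE 0.46) and Yp3 (-3.06, SE 0.52) fell as well. Both eggshell lists passed the list test with an estimated correlation (adjusted p = 0.0457 for each), the only lists to do so in this comparison. With the replicate number as a block neither did (adjusted p = 0.190 for chorion and 0.169 for vitelline membrane genes with an estimated correlation).

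Some oocyte genes fell in young ovaries, by smaller amounts than the eggshell genes. Of 45 maternal axis and egg activation genes 6 fell and none rose (median -0.96, adjusted p = 0.831 with an estimated correlation), and 26 fell and 3 rose with the replicate number as a block (adjusted p = 0.628). The 6 included the cell cycle regulators plu (-2.16, SE 0.43), gnu (-1.56, SE 0.42) and twe (-2.82, SE 0.70). The Polo inhibitor mtrm fell by 2.57 (SE 0.53), from 764 ± 3.00 to 129 ± 28 TPM, while the meiotic chromosome genes sunn (2.28, SE 0.37), corolla (2.04, SE 0.42) and hdm (1.28, SE 0.26) rose. In the 31 early germline genes Rbp9 (2.64, SE 0.59) and the ribosomal protein copy RpS19b (3.03, SE 0.74) rose and the germ plasm gene pgc fell by 1.88 (SE 0.43). Of 32 piRNA genes fs(1)Yb (3.08, SE 0.56) and shu (1.27, SE 0.27) rose. With the block the meiosis list had 7 rises and 7 falls, the early germline list 5 and 7, and the piRNA list 8 and 3. Of 23 genes in the mRNA decay list only Caf1-105, a chromatin assembly factor gene, fell (-1.74, SE 0.51, not called when adjusted over the list alone). With the block 9 fell and 1 rose, and the list median of -0.17 became 0.11 with equal library medians. None of 15 Ski and exosome genes passed (median 0.46), and 7 rose with the block.

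Somatic transcripts of the muscle sheath, blood cells and early follicle cells were higher in young ovaries. Of 24 muscle genes 18 rose and none fell (median 3.41, adjusted p = 0.126 with an estimated correlation), with the actin Act87E at 266 ± 88.5 against 7.79 ± 1.59 TPM (4.90, SE 0.52), the troponins TpnC73F (4.19, SE 0.45) and up (3.55, SE 0.39), and Act57B (4.05, SE 0.51). Of 17 hemocyte and basement membrane genes 11 rose and 1 fell (median 2.85, adjusted p = 0.249 with an estimated correlation), with the matrix gene Ppn (5.57, SE 0.97), SPARC (3.61, SE 0.58) and the phagocytosis receptor NimC4 (5.13, SE 0.57) up and crq down (-1.94, SE 0.42). Of 27 early follicle cell genes 9 rose and none fell (median 1.36, adjusted p = 0.831 with an estimated correlation), or 16 and 1 with the block, among them the signals Wnt4 (3.21, SE 0.47), hh (1.94, SE 0.32) and upd1 (1.81, SE 0.36) and the receptor ptc (2.35, SE 0.45). The largest rises were CG32266 (7.53, SE 0.33), the chitinase gene Cht5 (7.06, SE 0.30), CG11852 (6.41, SE 0.62) and CG4115 (5.78, SE 0.47). CG14568 stood at 42.8 ± 20.9 TPM in young libraries and was listed at 0 in both adult libraries.

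Genes of undifferentiated germ cell ovaries, 770 tested members of a list drawn from the bam RNAi input, were higher in young ovaries with a median of 1.70, and 358 rose and 4 fell. CG7443 (3.72, SE 0.33), CG16820 (4.49, SE 0.40) and Gasp (4.40, SE 0.43) were members. With an estimated correlation the list did not pass (adjusted p = 0.126). It holds 19 of the 24 muscle genes and 16 of the 17 hemocyte genes, so germ cells and soma are mixed in it. Smaller lists moved little, with single calls in fat body (Tsf1 3.81, SE 1.05, and Obp99a 2.63, SE 0.72, rose and Lip4 -2.14, SE 0.50, fell), gut (Npc2f 2.37, SE 0.51, rose), glutathione (Cyp6a2 3.22, SE 0.65, rose and GstD3 -1.33, SE 0.39, fell), heat shock (Hsp26 -2.04, SE 0.46, fell) and antimicrobial genes (Def -3.79, SE 0.82, fell). No apoptosis, splicing or ribosomal protein gene passed. Still, 78 of 79 ribosomal protein genes had positive log2 fold changes, with a median of 0.57. That list had an adjusted p of 0.941 with an estimated correlation and 3.3e-05 with the preset one. With the block 39 of 79 ribosomal protein genes (adjusted p = 0.628 with an estimated correlation) and 6 of 32 splicing genes rose, and there were 3 rises and 5 falls in the apoptosis, 7 and 4 in the heat shock, 5 and 4 in the fat body and 2 and 7 in the glutathione list.

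In limma 703 genes rose and 280 fell of 8864 tested between young and adult wild type. With the replicate number as a block 1737 rose and 1585 fell, and these include all 983 genes called without it. Quantile normalization gave 584 rises and 431 falls. Equal library medians moved the median of all genes from -0.052 to 0.231, and the list changes above are to be read against that shift. Leaving out 1 library gave 360 (young 1), 337 (young 2), 384 (adult 1) and 324 (adult 2) called genes. Age and egg chamber stages changed together in this comparison, which cannot separate them.

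Ovaries of the tst mutant had less eggshell mRNA than adult wild type, some muscle and blood cell genes rose, and the largest single rises were in other genes. Rpt6R, a proteasome subunit copy, was at 68.6 ± 9.35 TPM in 2 mutant libraries and 0.641 ± 0.0732 TPM in 2 adult wild type libraries (log2 fold change 5.40, SE 0.51, adjusted p = 6.12e-04), and its relative Rpt3R rose too (3.52, SE 0.41). The oxidoreductase gene Drat (5.06, SE 0.77), the reductase-like gene CG3397 (4.93, SE 0.53), the noncoding RNA lncRNA:CR44138 (4.87, SE 0.40) and CG14692 (4.54, SE 0.36) followed. Lactate dehydrogenase Ldh rose by 4.01 (SE 0.39), from 1.30 ± 0.0398 to 36.6 ± 9.22 TPM. Of 26 glutathione and detoxification genes 6 rose and none fell (median 0.92, adjusted p = 0.226 with an estimated correlation), with Cyp6a20 (3.49, SE 0.50), Cyp6a23 (2.10, SE 0.36), GstD5 (3.62, SE 0.69) and GstE5 (2.35, SE 0.51) among them, and 12 rose and 1 fell with the replicate number as a block.

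Chorion genes fell in the tst mutant with a smaller median than in young ovaries. Of 16 chorion genes 8 fell and none rose (median -3.23, adjusted p = 0.128 with an estimated correlation), and Cp36 fell by 3.09 (SE 0.45, adjusted p = 0.00468), from 7785 ± 2114 to 896 ± 81.1 TPM. Cp19 (-4.08, SE 0.97), Cp16 (-3.64, SE 0.72) and Cp38 (-3.27, SE 0.58) fell by similar amounts. Of 15 vitelline membrane genes 7 fell (median -2.13, adjusted p = 0.219 with an estimated correlation), including CG13083 (-3.53, SE 0.59) and Vm32E (-2.92, SE 0.48). Adjusted over the list alone, 13 chorion genes and 7 vitelline membrane genes fell, and with the replicate number as a block 14 and 10. Yolk protein transcripts did not pass, and Yp2 was at 5400 ± 1497 against 4217 ± 1217 TPM (0.36, SE 0.46, adjusted p = 0.782). No maternal axis gene passed (list median -1.14, adjusted p = 0.492 with an estimated correlation), with osk at 780 ± 492 against 1343 ± 250 TPM (-0.93, SE 0.75, adjusted p = 0.602). With the block 28 maternal axis genes fell and 1 rose (list adjusted p = 0.368 with an estimated correlation). A pair of germline regulators fell, pgc (-1.81, SE 0.43) and the piRNA factor moon (-1.69, SE 0.32), while the meiotic genes corolla (1.80, SE 0.42) and sunn (1.54, SE 0.37) and the piRNA gene fs(1)Yb (2.75, SE 0.56) rose.

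Some muscle and blood cell genes rose in the tst mutant. In the muscle list 10 of 24 genes rose (median 2.11, adjusted p = 0.226 with an estimated correlation), with TpnC73F (2.97, SE 0.45), Act87E (2.44, SE 0.52), wupA (2.38, SE 0.49) and up (2.33, SE 0.39). Of 17 hemocyte genes 3 rose (median 2.18, adjusted p = 0.219 with an estimated correlation), the peroxidasin Pxn (3.45, SE 0.80), Ppn (3.85, SE 0.97) and SPARC (2.54, SE 0.58), and 16 rose when adjusted over the list alone. The lipase gene Lip4 (3.21, SE 0.50) rose and the small heat shock gene Hsp26 fell by 1.85 (SE 0.46). In early follicle cells upd1 alone rose (1.68, SE 0.36). With the block 20 muscle, 15 hemocyte, 12 fat body and 13 early follicle cell genes rose, the last 2 lists with 1 fall each. No gene of the mRNA decay (median -0.33), Ski and exosome (0.24), ribosomal protein (0.50), gut, testis, apoptosis, splicing or antimicrobial lists passed. With the block 14 ribosomal protein, 5 gut and 5 antimicrobial genes rose, 7 mRNA decay genes fell, 5 apoptosis genes rose and 2 fell, and no splicing gene passed. The decapping activator me31B was at 1391 ± 892 against 3272 TPM (-1.39, SE 0.48, adjusted p = 0.129) and the antimicrobial gene Drs at 420 ± 35.4 against 14.9 TPM (5.25, SE 1.67, adjusted p = 0.0997). Among undifferentiated germ cell list genes 158 rose and 3 fell (median 1.63, adjusted p = 0.128 with an estimated correlation), and 528 rose and 4 fell when adjusted over the list alone, or 572 and 4 with the block. The median was 2.03 between replicates 1 and 1.27 between replicates 2.

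In all, 315 genes rose and 60 fell in the tst mutant, and 1442 rose and 640 fell with the replicate number as a block. Mutant and adult wild type differ in labelled genotype beyond tst, so stock differences cannot be separated from loss of tst here. Quantile normalization gave 170 rises and 161 falls, and a fit of the 2 groups alone 82 genes. The count of 375 depended on single libraries, with 52 (without tst mutant 1), 579 (without tst mutant 2), 29 (without adult 1) and 52 (without adult 2) called genes. The mutant carries a deficiency over tst, and 12 of 13 genes around it, tst included, had negative log2 fold changes, among them RanBP3 (-1.60), Hrd3 (-1.46) and Nup98-96 (-1.33), while Lsd-1 rose by 2.27 (adjusted p = 0.0281). These neighbours were chosen after their values were seen.

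**Figure D1:**
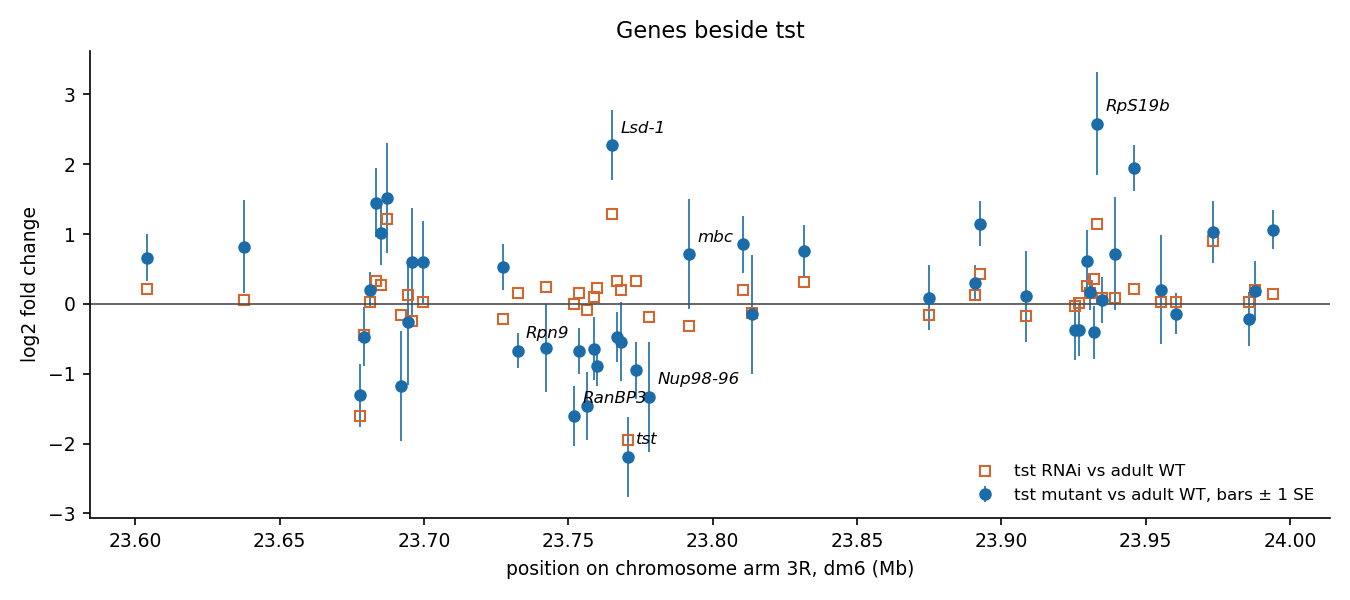
Log2 fold change against adult wild type with bars of 1 SE for genes beside tst, against position on chromosome arm 3R in Mb (dm6), in the tst mutant (circles) and tst RNAi (squares). The median of the tested genes around tst was -0.504 in the mutant and 0.157 in RNAi.

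In tst RNAi ovaries some muscle and blood cell genes rose as deposited, and no eggshell gene passed. Of 31 early germline genes 1 rose (median -0.06, mean 0.25). CG7443 rose by 3.50 (SE 0.33, adjusted p = 6.44e-04), from 56.4 ± 5.49 TPM in 2 adult wild type libraries to 654 ± 131 TPM in 2 tst RNAi libraries, and CG31300 by 3.17 (SE 0.29, adjusted p = 6.24e-04). RpL22-like, a germ cell copy of a ribosomal protein, rose by 3.33 (SE 0.50), from 0.0965 ± 0.0409 to 11.0 ± 6.69 TPM. The spermatocyte regulator dany (4.46, SE 0.79), CG15068 (4.77, SE 0.94), CG11852 (4.47, SE 0.62), CG13067 (4.12, SE 0.65) and CG8012 (3.83, SE 0.70) were among the largest rises, with CG5867 (3.69, SE 0.53) and CG17190 (3.67, SE 0.47) behind them. In the muscle list 9 of 24 genes rose (median 2.27, adjusted p = 0.0712 with an estimated correlation), with TpnC73F (3.27, SE 0.45), wupA (2.82, SE 0.49), up (2.79, SE 0.39) and Act57B (2.79, SE 0.51). Of 17 hemocyte genes 3 rose (median 1.92, adjusted p = 0.098 with an estimated correlation), the prophenoloxidase PPO1 (3.91, SE 0.76), NimC1 (3.19, SE 0.55) and Sr-CI (2.71, SE 0.55). With the replicate number as a block 17 muscle and 10 hemocyte genes rose, and with equal library medians 3 and 0. CG6908 fell by 2.67 (SE 0.55), and Syt4, at 2.95 TPM in adult wild type, was listed at 0 in both tst RNAi libraries.

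No single eggshell, oocyte or decay gene passed in tst RNAi, but all 16 chorion and all 15 vitelline membrane genes had negative log2 fold changes. The chorion median was -0.93 (adjusted p = 0.262 with an estimated correlation, 3.99e-07 with the preset one), with Cp36 at 4701 ± 1414 TPM (-0.73, SE 0.45, adjusted p = 1.00) and Cp38 at 6560 ± 2132 TPM (-0.75, SE 0.58). None of 45 maternal axis genes passed (median -0.16), with osk at 1110 ± 320.0 TPM (-0.29, SE 0.75) and nos at 322 ± 102 TPM (-0.32, SE 0.79). The vitelline membrane list had a median of -0.67 (adjusted p = 0.347 with an estimated correlation, 2.90e-05 with the preset one). With the block 1 chorion and 1 vitelline membrane gene fell. The mRNA decay (median -0.09), ribosomal protein (0.09), heat shock (0.12), piRNA (0.10), meiosis (-0.03), splicing (0.03), apoptosis (-0.03), glutathione (0.23), fat body (1.52), gut (1.56) and antimicrobial (0.75) lists held no called gene, while with the block 8 fat body genes and 1 each of the meiosis, glutathione and antimicrobial lists rose. Medians of the Ski and exosome (0.02) and early follicle cell (0.00) lists turned negative with equal library medians. The antimicrobial genes Drs, at 138 ± 37.7 TPM (3.63, SE 1.67, adjusted p = 0.649), and Def (2.45, SE 0.82, adjusted p = 0.260), varied too much to pass.

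The eye color gene w, the marker of the labelled transgenes, rose by 5.99 (SE 0.45) to 80.7 ± 5.17 TPM in tst RNAi. It was at 0.362 and 0.213 TPM in adult and 0.870 and 0.216 TPM in young wild type, although their labels list w+ marked UAS-Dcr-2 and nanos-GAL4. Dcr-2, chosen after its values were seen, was at 42.8 and 60.3 TPM in adult wild type and 37.3 and 61.6 TPM in tst RNAi. It was at 601 TPM in control input 1, which has the same labelled genotype as adult wild type. The adult wild type stock may thus differ from tst RNAi in more than the RNAi, and such a difference was not tested.

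Among undifferentiated germ cell list genes 66 rose and 1 fell in tst RNAi (median 1.17, adjusted p = 0.0712 with an estimated correlation), and 311 rose and 2 fell when adjusted over the list alone. Over all genes 83 rose and 7 fell, and 387 rose and 42 fell with the replicate number as a block, 293 and 1 of them in the list. Quantile normalization gave 40 rises and 24 falls, and equal library medians 24 and 2. Leaving out 1 library reduced the count of 90 to 3 (tst RNAi 1), 12 (tst RNAi 2), 3 (adult 1) and 5 (adult 2). The list median was 1.28 between replicates 1 and 1.06 between replicates 2.

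Few genes passed in pelo mutant ovaries in the main fit, and nearly all of them rose. Lactate dehydrogenase Ldh rose by 4.38 (SE 0.39, adjusted p = 9.77e-04), from 0.487 ± 0.157 TPM in 2 heterozygote libraries to 30.0 ± 1.12 TPM in 2 mutant libraries. CG12355 (3.76, SE 0.47), the transporter gene MFS3 (3.45, SE 0.41), CG13659 (3.19, SE 0.45) and CG10559 (3.13, SE 0.40) rose. RpL22-like rose by 3.31 (SE 0.50), from 0.0211 ± 0.0299 to 9.35 ± 3.17 TPM, and CG7443 by 2.52 (SE 0.33), from 49.3 ± 21.8 to 275 ± 25.2 TPM. Of 24 muscle genes TpnC73F (2.87, SE 0.45) and up (2.27, SE 0.39) rose (list median 1.75, adjusted p = 0.0869 with an estimated correlation), and 13 rose when adjusted over the list alone. The only fall was CG5096 (-2.71, SE 0.44), from 49.6 ± 1.23 to 6.73 ± 0.273 TPM.

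In the main fit no list passed with an estimated correlation in pelo mutants, and most lists held no called gene. Of 26 glutathione genes none passed, and 8 rose when adjusted over the list alone (median 0.98, adjusted p = 0.0869 with an estimated correlation), with GstE6 at 379 ± 118 against 156 TPM (1.27, SE 0.37, adjusted p = 0.252). Of 14 gut genes none passed, and 8 rose when adjusted over the list alone (median 3.26, adjusted p = 0.0869 with an estimated correlation), but the trypsin gene betaTry at 95.8 ± 134 TPM was high in 1 of 2 libraries. Chorion (median -1.33, adjusted p = 0.0967) and vitelline membrane genes (median -1.21, adjusted p = 0.104 with an estimated correlation) held no called gene, with Cp36 at 1852 ± 1029 against 4774 ± 1800 TPM (-1.43, SE 0.45, adjusted p = 0.303). Antimicrobial genes had a median of 1.17 (adjusted p = 0.197 with an estimated correlation), with Drs at 4.74 (SE 1.67, adjusted p = 0.395) and Def at 3.20 (SE 0.82, adjusted p = 0.185), and hemocyte genes one of 1.15 (adjusted p = 0.197 with an estimated correlation). Maternal axis (-0.31), mRNA decay (-0.19), meiosis (-0.06), ribosomal protein (0.28), Ski and exosome (0.00), fat body (0.73) and apoptosis (0.06) lists held no called gene, and osk was at 1041 ± 909 against 1177 ± 1002 TPM. The piRNA, early follicle cell, testis, heat shock and splicing lists held none either, and their medians changed sign between scalings.

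In the pelo mutant 5 undifferentiated germ cell list genes rose and none fell (median 0.99, adjusted p = 0.0869 with an estimated correlation), and 143 rose and 1 fell when adjusted over the list alone. Over all genes 19 rose and 1 fell, while 677 had an unadjusted p below 0.05. Quantile normalization gave 10 rises and 4 falls, equal library medians 1 rise and no fall, and a fit of the 2 groups alone 0 genes in limma. With the replicate number as a block, which is tied to no other label here, 329 rose and 30 fell. Deviations of heterozygote and mutant libraries with the same number correlated at 0.653, so the main fit may leave out a pairing. Without 1 library the count was 3 (mutant 1), 34 (mutant 2), 3 (heterozygote 1) and 4 (heterozygote 2). The pelo mutant libraries had the largest replicate difference of all pairs, a median of 0.838 log2.

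Mutation of hfp raised and lowered single genes with large changes, among them 1 testis, 1 meiosis and 1 piRNA gene. CG14932 rose by 6.23 (SE 0.55, adjusted p = 4.39e-04), from 1.71 ± 1.10 TPM in 2 heterozygote libraries to 234 ± 185 TPM in 2 mutant libraries. CG13540 (6.30, SE 0.74), the ATP synthase copy ATPsynepsilonL (5.63, SE 0.60), hog (5.40, SE 0.65), the glutathione transferase GstD5 (5.06, SE 0.69), the spermatocyte RNA-binding gene Rbp4 (4.14, SE 0.55), CG14346 (4.08, SE 0.59), the receptor gene otk2 (3.95, SE 0.50) and CG12851 (2.67, SE 0.28) rose. The cohesion gene ord rose by 3.06 (SE 0.31), from 0.229 ± 0.103 to 9.27 ± 0.412 TPM, and the testis TAF gene Taf12L by 3.24 (SE 0.51), from 9.56 ± 6.53 to 89.2 ± 13.5 TPM. The heterochromatin protein gene rhi, which marks piRNA clusters, fell by 2.94 (SE 0.41), from 44.0 ± 12.7 to 4.80 ± 1.08 TPM. CG4408 (-5.67, SE 0.34), CG3397 (-5.47, SE 0.53), CG5568 (-4.97, SE 0.66), the oxidase Duox (-4.68, SE 0.73), CG40006 (-4.26, SE 0.64), CG2187 (-4.08, SE 0.53), CG8420 (-3.96, SE 0.50) and CG31262 (-3.74, SE 0.72) fell.

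In the main fit few genes passed by list in the hfp mutant, and no list passed with an estimated correlation. Of 24 muscle genes 3 rose, Mlp60A (2.19, SE 0.42), TpnC73F (2.36, SE 0.45) and up (2.13, SE 0.39), with a median of 2.02 (adjusted p = 0.199 with an estimated correlation), and 15 rose when adjusted over the list alone. No hemocyte gene passed (median 1.12, adjusted p = 0.471 with an estimated correlation). Chorion (-1.01), vitelline membrane (-0.89) and maternal axis genes (-0.81) held no called gene (adjusted p = 0.649 each with an estimated correlation), with Cp36 at 2563 ± 373 against 5279 ± 1193 TPM (-1.03, SE 0.45) and osk at 1053 ± 337 against 1506 ± 180 TPM (-0.55, SE 0.75). In the testis list Taf12L alone rose, the list median was -0.23 and its mean 0.30, and the meiosis list (median -0.53) held ord alone. No gene passed in the early germline (-0.41), mRNA decay (-0.34), Ski and exosome (0.19), heat shock (-0.52), ribosomal protein (0.28), fat body (0.19), gut (0.33) or antimicrobial (0.55) lists. The early follicle cell, apoptosis and splicing lists held no called gene, and their medians changed sign with the scaling, as did that of the piRNA list with rhi.

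Among undifferentiated germ cell list genes 24 rose and 1 fell in hfp mutants (median 1.15, adjusted p = 0.199 with an estimated correlation), and 200 rose and 2 fell when adjusted over the list alone. Over all genes 56 rose and 32 fell. Quantile normalization gave 36 rises and 44 falls, and a fit of the 2 groups alone 0 genes in limma. With the replicate number as a block, which is tied to no other label here, 511 rose and 364 fell. Deviations of heterozygote and mutant libraries with the same number correlated at 0.717, so the main fit may leave out a pairing. Equal library medians moved the median of all genes from -0.074 to 0.153. Leaving out 1 library gave 33 (mutant 1), 278 (mutant 2), 23 (heterozygote 1) and 29 (heterozygote 2) called genes. The list median was 1.48 between replicates 1 and 0.78 between replicates 2, and 0.697 without hfp mutant 1.

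**Figure D2:**
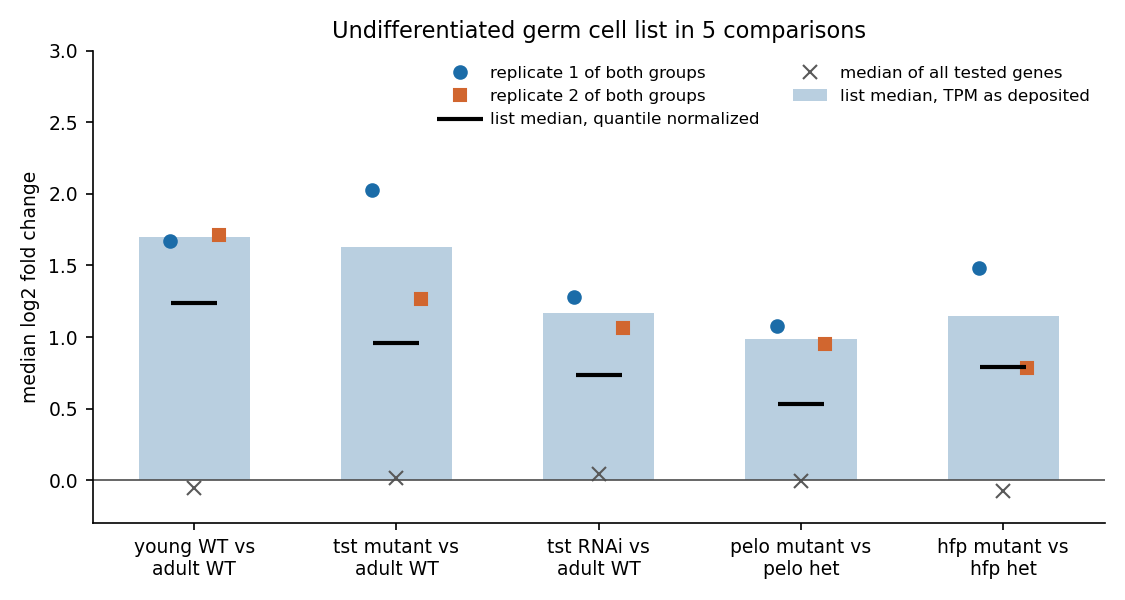
Median log2 fold change of the undifferentiated germ cell list in 5 comparisons (bars), with the values within replicates 1 (circles) and 2 (squares), after quantile normalization (dashes) and for all genes (crosses). The list medians were 1.70 in young wild type, 1.63 in the tst mutant, 1.17 in tst RNAi, 0.99 in pelo and 1.15 in hfp mutants.

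The muscle genes TpnC73F and up and the gene CG7443 rose in all 3 of tst RNAi, pelo and hfp ovaries. RpL22-like rose in tst RNAi and pelo (hfp 2.12, SE 0.50, adjusted p = 0.0758). CG14346, CG31300, Mlp60A and Phk-3 rose in tst RNAi and hfp, and CG12355 rose in pelo and hfp. These 9 genes rose in 2 or more of the 3 comparisons. Of them, TpnC73F (4.19), up (3.55), CG7443 (3.72), Mlp60A (2.60), CG12355 (2.49) and Phk-3 (1.78) also rose in young wild type. Their rise is thus not particular to loss of tst, pelo or hfp. In young wild type RpL22-like (0.37), CG14346 (0.20) and CG31300 (-0.32) did not pass. Tst RNAi and pelo shared 4 rises where 0.178 were expected (Fisher adjusted p = 4.98e-05), tst RNAi and hfp 7 against 0.524 (adjusted p = 1.96e-06), and pelo and hfp 4 against 0.12 (adjusted p = 1.15e-05). Across all genes the log2 fold changes of these pairs correlated at 0.604, 0.540 and 0.541. Leaving out 1 library moved the count of 9 to 65 without hfp mutant 2, to 14 without hfp mutant 1, to 4 without either hfp heterozygote or without tst RNAi 2, to 3 without tst RNAi 1 and to 2 without either adult library.

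The tst mutant shared 11 rises with pelo (0.675 expected, correlation 0.694) and 22 with hfp (1.99 expected, correlation 0.646), pairs without a common control and with simulated correlations of 0.001 and 0.003. Young wild type shared 7 rises with pelo (1.51 expected, correlation 0.516) and 13 with hfp (4.44 expected, correlation 0.465), again without a common control. The pairs that follow share the adult wild type libraries. Young wild type and the tst mutant shared 125 rises where 24.98 were expected, and 45 falls where 1.90 were expected, and their fold changes correlated at 0.680. Correlation of 0.499 arises from shared controls alone, by simulation. The tst mutant and tst RNAi shared 45 rises (2.95 expected, correlation 0.647 against 0.502 simulated), and young wild type and tst RNAi 47 (6.58 expected, correlation 0.506 against 0.5 simulated). After the simulated part from shared controls was taken off, covariances of 0.591, 0.216 and 0.222 were left in these pairs. The simulation left out the replicate number, though deviations of same-number libraries correlated at 0.613 to 0.762 in these groups. The part taken off is therefore uncertain.

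**Figure D3:**
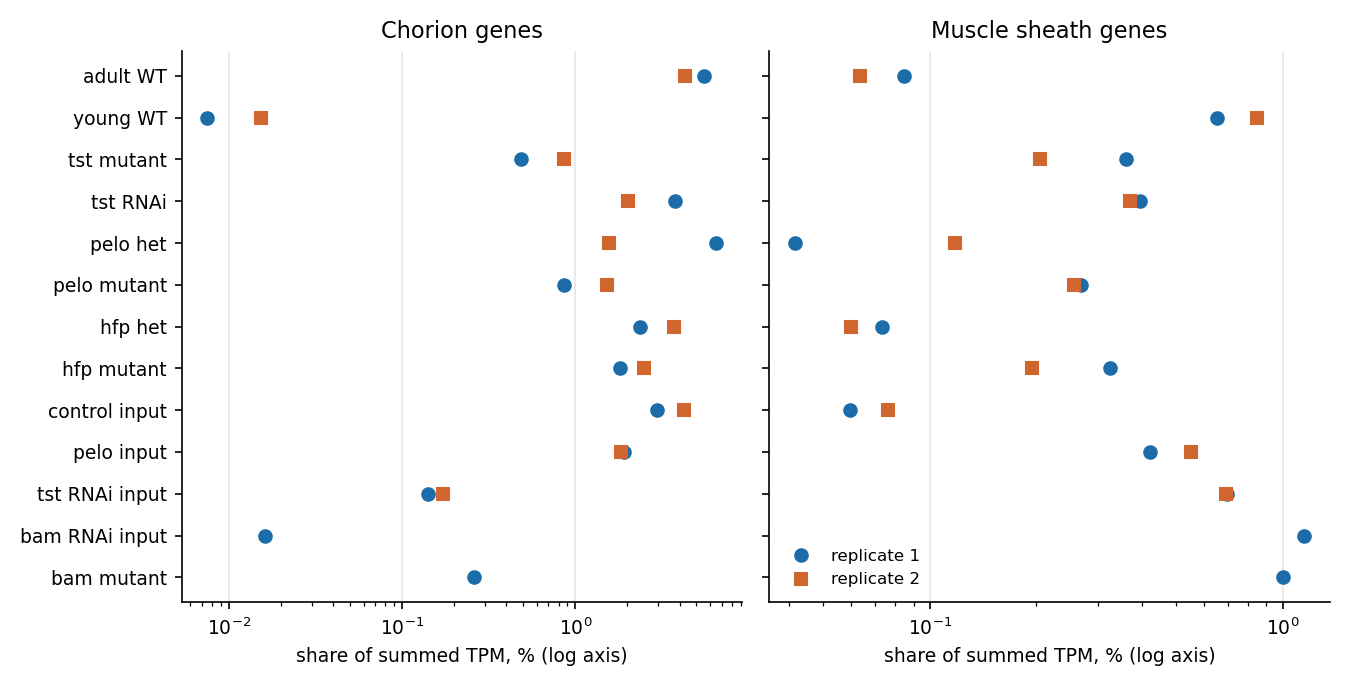
Share of chorion and of muscle sheath genes in the summed TPM (percent, log axis) of each library by group, replicate 1 as circles and 2 as squares. Chorion genes took 5.50 and 4.31 percent in adult and 0.00749 and 0.0154 percent in young wild type, and muscle genes 0.0845 and 0.0636 against 0.653 and 0.848 percent.

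In the separate input libraries tst RNAi ovaries showed both lost eggshell and oocyte mRNA and raised muscle and blood cell mRNA, with single immune and heat shock genes among the largest rises. The antimicrobial gene Drs rose by 6.53 (SE 0.85), from 9.60 ± 10.2 TPM in 2 control inputs to 759 ± 347 TPM in 2 tst RNAi inputs, and Def by 5.40 (SE 0.38). Of 17 antimicrobial genes 5 rose and none fell, with a median of 0.77 that turned to -0.07 with quantile normalization. Among 17 heat shock genes 6 rose and 1 fell (median 0.66, adjusted p = 0.677 with an estimated correlation), with Hsp67Ba up by 4.65 (SE 0.29). Hsp67Bc at 190 ± 213 TPM (6.22, SE 0.95) and Hsp68 at 244 ± 277 TPM (5.97, SE 0.96) differed widely between the 2 tst RNAi libraries. Both libraries stood above both control inputs, where the means were 0.667 TPM for Hsp67Bc and 1.40 TPM for Hsp68. CG43112 (5.66, SE 1.12), CG17127 (5.58, SE 0.58), CG4415 (5.40, SE 0.38) and CG18628 (5.33, SE 1.04) also rose. In the apoptosis list, with 5 rises and 6 falls and a median of -0.38, rpr (2.58, SE 0.28), Xrp1 (2.23, SE 0.33) and hid (1.43, SE 0.28) rose. Irbp fell by 1.56 (SE 0.22).

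Oocyte and eggshell genes fell in tst RNAi inputs. Of 45 maternal axis genes 32 fell and none rose (median -1.80, adjusted p = 0.280 with an estimated correlation), with plu (-3.01, SE 0.24), twe (-2.72, SE 0.23), gnu (-2.21, SE 0.22) and the yolk receptor yl (-1.91, SE 0.20). The posterior determinant nos fell by 2.55 (SE 0.37), from 438 ± 111 to 73.6 ± 14.9 TPM, and the nos repressor smg by 3.22 (SE 0.58). Of 16 chorion genes 15 fell and 1 rose (median -4.12, adjusted p = 0.144 with an estimated correlation), among them Cp15 (-6.24, SE 1.17), Cp18 (-6.21, SE 0.76), Cp16 (-5.92, SE 0.99) and Cp38 (-4.17, SE 0.45). Of 15 vitelline membrane genes 11 fell (median -2.19, adjusted p = 0.153 with an estimated correlation). Among 23 genes in the mRNA decay list 10 fell and none rose (median -0.68, adjusted p = 0.401 with an estimated correlation). They included Patr-1 (-1.60, SE 0.31) and Caf1-105 (-2.04, SE 0.24), a chromatin assembly factor gene. Of 29 meiosis genes 14 fell and 5 rose (median -0.74). Among them mtrm fell (-3.12, SE 0.34), and the synaptonemal gene cona (3.16, SE 0.31) and the meiotic gene sunn (2.45, SE 0.26) rose. In the early germline list 13 fell and 5 rose (median -0.40, 0.05 with equal library medians), with RpL22-like (16.5 ± 2.29 against 0.0941 ± 0.133 TPM, adjusted p = 8.60e-06), RpS19b (3.03, SE 0.30) and the testis RNA-binding gene blanks (2.89, SE 0.30) up and png (-2.13, SE 0.25) down. Of 32 piRNA genes 7 fell and 3 rose (median -0.27, 0.18 with equal library medians), with rhi (-1.89, SE 0.24) down and fs(1)Yb (2.67, SE 0.43) up.

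Somatic genes rose in tst RNAi inputs beside these changes. Among 24 muscle genes 21 rose (median 3.34, adjusted p = 0.134 with an estimated correlation), with Mlc1 at 422 ± 11.6 against 29.4 ± 0.733 TPM (3.80, SE 0.19), TpnC73F (4.37, SE 0.25) and wupA (3.88, SE 0.24). Of 17 hemocyte genes 16 rose (median 2.80, adjusted p = 0.153 with an estimated correlation), with Pxn (4.73, SE 0.41) and Sr-CI (3.53, SE 0.36). Among 27 early follicle cell genes 16 rose and 4 fell (median 1.31, adjusted p = 0.401 with an estimated correlation), with eya (2.71, SE 0.38), cas (2.66, SE 0.33) and Wnt4 (2.66, SE 0.31) up. Glutathione genes had 10 rises and 1 fall of 25 (median 0.41), and ribosomal proteins 3 rises of 79 (median 0.49, 1 rise when adjusted over the list alone, 33 with equal library medians), led by RpS5a (1.18, SE 0.21). Fat body genes had 4 rises and 3 falls of 14 (median 0.71) and gut genes 3 rises of 9 (median 1.17). Testis (2 rises and 2 falls), apoptosis (5 rises and 6 falls) and splicing lists (2 rises and 3 falls) had medians that changed sign between scalings, and 1 of 15 Ski and exosome genes, tst, fell.

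Of 765 undifferentiated germ cell list genes 702 rose and none fell in tst RNAi inputs (median 2.31, adjusted p = 0.0315 with an estimated correlation), but the list was drawn against these same control inputs and is not independent evidence here. Over all 8572 genes 1600 rose and 1827 fell. Equal library medians gave 2324 rises and 968 falls and moved the median of all genes from -0.158 to 0.288. With 1 library left out there were 1998 (tst RNAi 1), 1912 (tst RNAi 2), 1979 (control 1) and 2588 (control 2) called genes of 3427. The control inputs differed in labelled genotype, a driver line and a pelo heterozygote, and w was at 146 TPM in control input 1 and 12.9 TPM in control input 2. Of 81 genes that rose in the total mRNA comparison and were tested here, 74 rose again (14.9 expected, Fisher p = 9.76e-47), while of 3 falls none was shared. A shift shared by many list genes could give such an overlap, since Fisher's test treats genes as independent.

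Inputs of pelo mutants held more antimicrobial and muscle mRNA. Def rose by 6.15 (SE 0.38, adjusted p = 8.27e-06), from 1.99 ± 0.0671 TPM in 2 control inputs to 212 ± 22.5 TPM in 2 pelo inputs. Of 17 antimicrobial genes 10 rose and none fell (median 2.73), with Drs (5.63, SE 0.85), AttB (4.46, SE 0.34), Dro (4.15, SE 0.41) and AttA (3.65, SE 0.48), and the list passed with an estimated correlation (adjusted p = 0.0193). CG43074 (6.55, SE 1.09), CG4415 (6.38, SE 0.38), CG43090 (6.37, SE 1.31), the spermathecal protease Send1 (6.09, SE 1.47) and the iron carrier Tsf1 (5.41, SE 1.17) rose. RpL22-like rose by 4.83 (SE 0.26), from 0.0941 ± 0.133 to 30.1 ± 1.65 TPM, and RpS19b by 2.39 (SE 0.30). Of 24 muscle genes 20 rose (median 2.62, adjusted p = 0.0477 with an estimated correlation), with Mlc1 (3.06, SE 0.19) and TpnC73F (3.51, SE 0.25). Of 17 hemocyte genes 13 rose (median 1.93, adjusted p = 0.228 with an estimated correlation), with Pxn (4.49, SE 0.41).

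Falls in pelo inputs were fewer. CG4267 fell by 3.58 (SE 0.49) and CG14187 by 2.41 (SE 0.38), and the vitelline gene Fcp3C by 1.97 (SE 0.55). Of 45 maternal axis genes 6 fell and none rose (median -0.75, adjusted p = 0.407 with an estimated correlation), with nos (-1.29, SE 0.37) among the decay and piRNA lists. In the meiosis list c(3)G (-1.59, SE 0.25) and polo (-0.84, SE 0.18) fell and vilya (1.18, SE 0.27) rose. Chorion (median -0.89, 2 falls), vitelline membrane (-0.63, 2 falls) and mRNA decay lists (-0.46, 2 falls, none when adjusted over the list alone) changed in part. So did the early germline (-0.43, 4 rises and 1 fall) and ribosomal protein lists (0.64, 1 rise). The falls in the decay list were Caf1-105 and nos. Glutathione genes had 7 rises and 1 fall of 25 (median 0.56, adjusted p = 0.0676 with an estimated correlation), with GstE9 up (2.69, SE 0.52) and GstE1 down (-1.10, SE 0.22). Fat body genes had 4 rises (median 0.69), and in the apoptosis list rpr (1.57, SE 0.28) and Xrp1 (1.88, SE 0.33) rose (median -0.32). In the Ski and exosome list (median 0.33) Rrp46 rose (0.98, SE 0.26) and pelo fell. The piRNA, early follicle cell, gut, testis, heat shock and splicing lists had medians that changed sign between scalings.

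Of 765 undifferentiated germ cell list genes 484 rose and 1 fell in pelo inputs (median 1.56, adjusted p = 0.0213 with an estimated correlation), again not independent of the control inputs. Over all genes 885 rose and 159 fell. Quantile normalization gave 599 rises and 315 falls, and equal library medians moved the median of all genes from -0.142 to 0.109. With 1 library left out there were 777 (pelo 1), 500 (pelo 2), 514 (control 1) and 1002 (control 2) called genes of 1044. Of 19 genes that rose in the total mRNA comparison 18 rose again (1.97 expected, Fisher p = 2.78e-17), and its 1 fall was not shared. Here too the Fisher test treats genes as independent.

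On polysomes of control ovaries, ribosomal protein mRNAs took a larger share than in input, while most other called genes took a smaller one as deposited. CG9034 was at 89.3 TPM in input and 452 TPM on polysomes (log2 ratio 2.33, SE 0.21, adjusted p = 0.00184, 2 libraries each), followed by ksh (2.12, SE 0.28), the complex I gene ND-B12 (1.98, SE 0.25), UQCR-Q (1.96, SE 0.36) and Vm32E (1.82, SE 0.32). Of 79 ribosomal protein genes 28 rose and 1 fell (median 0.52, adjusted p = 0.340 with an estimated correlation), with RpL22 (1.15, SE 0.23), RpS26 (1.15, SE 0.25), RpLP2 (1.09, SE 0.24) and RpS4 (1.00, SE 0.22). With equal library medians 63 rose and none fell (median 1.30), and with quantile normalization 11 rose and 2 fell (median 0.20). Lower on polysomes were the cohesin loader Nipped-B (-2.55, SE 0.29), Vps11 (-2.55, SE 0.26), Mnt (-2.48, SE 0.38) and the kinase mnb (-2.38, SE 0.31). Of 45 maternal axis genes 32 fell and 1 rose (median -1.14), or 12 and 5 with equal library medians (median -0.36), with CycA (-1.95, SE 0.26) and bru1 (-1.85, SE 0.21).

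The median of all genes on control polysomes was -0.547 as deposited and 0.236 with equal library medians, with decay and early germline lists below it and eggshell lists above it as deposited. Of 23 mRNA decay genes 16 fell and none rose (median -1.33), with tral (-2.36, SE 0.34) and Edc3 (-2.11, SE 0.29), and the early germline list had 22 falls and 2 rises (median -1.16). Of 32 piRNA genes 24 fell (median -0.92), with AGO3 (-2.02, SE 0.21), and of 32 splicing genes 19 fell (median -0.93), with Hrb98DE (-1.67, SE 0.22). Meiosis genes had 14 falls (median -0.76, but 0.02 with equal library medians). With equal library medians 1 piRNA gene rose and 1 fell (median -0.14), 4 splicing genes fell (median -0.15), and the meiosis list had 1 rise and 2 falls, the decay list 1 and 5 and the early germline list 4 and 7. Quantile normalization left 5 falls in the piRNA and 8 in the splicing list. Vitelline membrane genes had 6 rises and 2 falls (median 0.14), and chorion genes 3 rises and 5 falls, with a median of 0.11, a mean of -0.15 and a median of -0.08 with quantile normalization. No list passed with an estimated correlation. In all 279 genes rose and 3293 fell, against 1324 and 567 with equal library medians and 889 and 801 with quantile normalization. Rises and falls here are relative to the other mRNAs of a library.

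As deposited, many ribosomal protein genes had a lower ratio of polysome to input in tst RNAi than in control ovaries, with a count that depended on the scaling. RpS29 went from 4652 TPM in input to 10620 TPM on polysomes in control ovaries and from 6417 to 2696 TPM in tst RNAi, a difference of log2 ratios of -2.36 (SE 0.38, adjusted p = 0.0166, 2 libraries per group). RpLP2 (-2.07, SE 0.34), RpL32 (-2.06, SE 0.35), RpS21 (-2.02, SE 0.35), RpS16 (-2.01, SE 0.35), RpS26 (-1.89, SE 0.35) and RpS12 (-1.87, SE 0.34) were lower in the same way. Of 79 ribosomal protein genes 47 were lower and none higher (median -1.13, adjusted p = 0.440 with an estimated correlation), against 18 lower with equal library medians (median -2.001) and 0 with quantile normalization (median -0.49). Higher ratios were found for CG31998 (2.90, SE 0.61), Mnt (2.75, SE 0.54), mav (2.67, SE 0.57) and SKIP (2.55, SE 0.48). Of 45 maternal axis genes 20 were higher and none lower (median 1.24, 0.36 with equal library medians, where none was called). They included the RNA-binding gene stau (2.35, SE 0.43) and gus (1.93, SE 0.33).

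Germline and decay genes had higher ratios as deposited, as did most called genes, and none in these lists was called under the other 2 scalings. The early germline list had 15 higher (median 1.22), with Sxl (2.24, SE 0.43), the piRNA list 15 (median 1.11), with AGO3 (1.88, SE 0.30), the mRNA decay list 12 (median 1.17), with Edc3 (2.05, SE 0.41), and the splicing list 14 (median 0.97), with sqd (2.21, SE 0.42). Meiosis (7 higher, median 0.88) and apoptosis genes (4 higher, median 0.99, with Irbp18 at 2.36, SE 0.31) followed. The median of all genes was 0.697 as deposited and -0.177 with equal library medians. In all 1889 genes were higher and 83 lower as deposited, 0 higher and 54 lower with equal library medians, and 0 in limma with quantile normalization. Leaving out 1 preparation gave 3152 (control 1), 2395 (control 2) and 0 (tst RNAi 1 or 2) called genes of 1972.

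**Figure D4:**
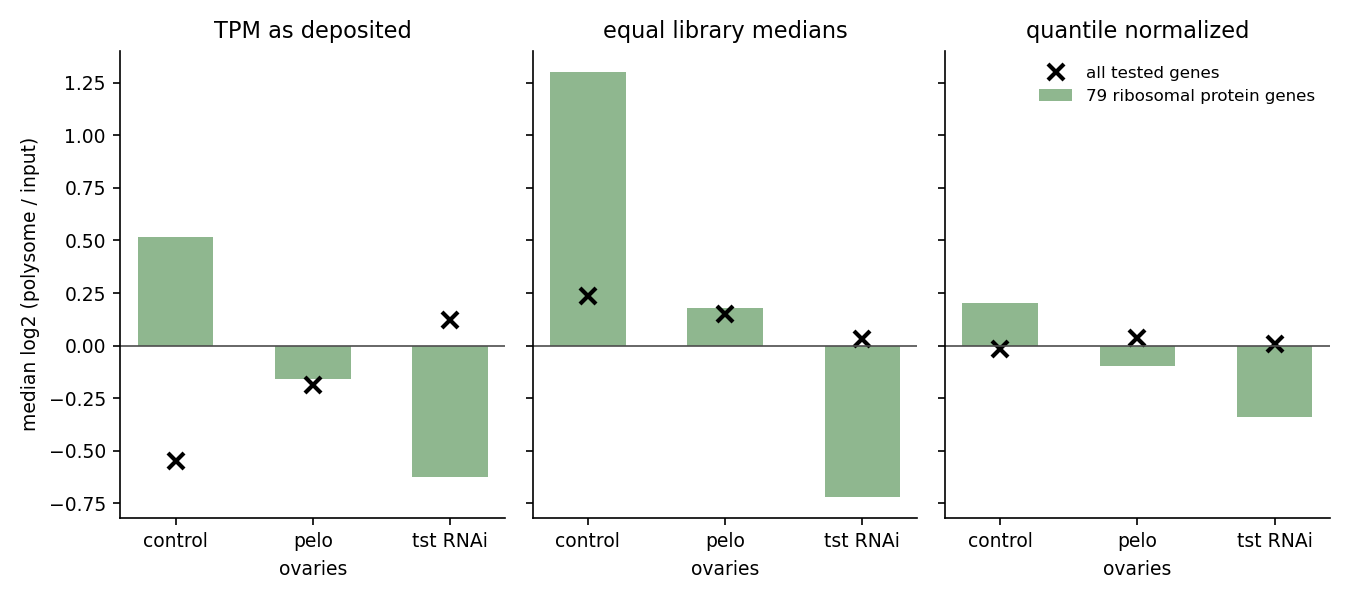
Median log2 ratio of polysome to input over 79 ribosomal protein genes (bars) and over all tested genes (crosses) in control, pelo and tst RNAi ovaries under 3 scalings. The tst RNAi median was -0.626 as deposited, -0.718 with equal library medians and -0.339 with quantile normalization.

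In pelo ovaries no gene differed from control in its ratio of polysome to input by limma, while 1140 genes had an unadjusted p below 0.05. RpL41, the most abundant ribosomal protein mRNA measured, had a difference of -0.95 (SE 0.55, adjusted p = 0.410), the germline helicase vas 0.91 (SE 0.28, adjusted p = 0.374) and Hrb87F 0.92 (SE 0.27, adjusted p = 0.374). The ribosomal protein list had a median of -0.64 (adjusted p = 0.663 with an estimated correlation), -1.09 with equal library medians and -0.35 with quantile normalization. The median of all genes moved from 0.402 to -0.045 with equal library medians. Leaving out control preparation 2 gave 1087 called genes, and leaving out any other gave 0.

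The bam libraries had 1 replicate each and are given as values. CG18628 was at 5374 TPM in the bam RNAi input and 504 TPM in the bam mutant, against 42.2 and 14.2 TPM in the control inputs. RpS19b was at 689 and 417 TPM against 3.72 and 3.14 TPM, the synaptonemal gene cona at 415 and 311 TPM against 2.71 and 2.30 TPM, and blanks at 194 and 146 TPM against 0.488 and 1.19 TPM. Def (519 TPM) and Drs (1759 TPM) were high in the bam RNAi input. Cp38 was at 12.6 TPM in the bam RNAi input and 1093 TPM in the bam mutant, against 5352 and 7885 TPM, and Cp15 at 30.7 and 18.2 TPM against 9165 and 13550 TPM. By list, the bam RNAi input differed from the control inputs by a median of -7.68 log2 for chorion, -2.14 for maternal axis, 3.68 for muscle and 3.61 for hemocyte genes, and the bam mutant by -4.40, -2.08, 3.77 and 3.82. Of 784 undifferentiated germ cell list genes, 660 also met the rule in the bam mutant, and the bam RNAi input and the bam mutant had a Spearman correlation of 0.935. In the library labelled bam RNAi polysome the chorion median was 6.26 above the input, with osk at 480 against 2.46 TPM and Cp36 at 2533 against 15.2 TPM. It also held more bam than its input, 18.9 against 3.10 TPM, so whether it matches its label is not settled.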

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

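The scalings were planned as alternatives, but their use as tests of the tst RNAi ratios and the test of ribosome loading were chosen only after the results were seen, and the other tests were set before their values were computed.

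The ratio of polysome to input differed between tst RNAi and control ovaries for 1972 genes, a difference between groups that no label names. Equal library medians kept 2.13 percent of these calls, but this scaling shifts all genes of a library alike and prompted the test, so a shift shared by all genes could not be told apart from other causes. For ribosomal protein genes the median difference was -2.001, with 18 genes called lower, under equal library medians and -0.489, with none called, under quantile normalization, so a scaling effect could not be told apart there either. A single outlying preparation as the cause of the ribosomal protein median was argued against, since at least 83.3 percent of it remained without each one. A change in translation of these mRNAs in tst RNAi ovaries remains open and was not tested against an independent measure.

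The effect of tst RNAi differed between the total mRNA and the input libraries for 94 genes, 64 with a larger and 30 with a smaller change in inputs, a difference between library sets under the same label. For pelo mutants the same test called 0 genes in limma. Control genotype, driver and dissection differ or are not given between the sets, and the cause was not tested.

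Median changes of the undifferentiated germ cell list were positive in tst mutant, tst RNAi, pelo and hfp ovaries, but the list passed in none with an estimated correlation (adjusted p = 0.128, 0.0712, 0.0869 and 0.199). Less eggshell and yolk mRNA in the TPM total was argued against, since rescaling without those genes kept at least 96.9 percent of each list median. This outcome followed from their small shares, so it adds no evidence beyond them. In adult wild type chorion genes took 5.50 and 4.31, vitelline membrane genes 3.95 and 3.34 and yolk genes 0.903 and 0.774 percent. A change like that from adult to young ovaries was argued against as the whole cause. The 65 members not higher in young ovaries had a median of at least 0.845 in pelo and hfp mutants. Of these 65, none was called as higher in pelo and 4 in hfp mutants. Age and egg chamber stage changed together in young ovaries, so a lower share of late egg chambers itself could not be excluded. A larger share of muscle and blood cells could not be told apart from a germ cell change, since the 12 early germline and meiosis members had medians of 1.82 (tst mutant), 0.649 (tst RNAi), 0.354 (pelo) and 1.23 (hfp), and without members of the somatic and stress lists, a setting added after seeing the data, the list medians were 1.573, 1.137, 0.959 and 1.131, though somatic genes outside those lists remain in it. Retained expression of early germ cell mRNA stays open.

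The library labelled bam RNAi polysome held oocyte and late follicle cell transcripts that its input lacked. A mislabelled sample without undifferentiated germ cells was argued against, since the undifferentiated germ cell list was 2.247 log2 above the higher control polysome library. A swap with another sample high in this list was not tested. Loading of the same mRNAs on ribosomes would not account for them, since the same 42 genes had a median ratio of -1.002 in control ovaries. RNA of another ovary sample mixed in could not be told apart from other causes, since the smallest SD of the ratio to another library was 0.586, against pelo input 1.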

How the results depend on the processing

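No alternative setting was chosen after seeing the data except the crossed pelo pairing and the undifferentiated germ cell list without somatic and stress genes. No named gene result reversed under any alternative. Of these results 8681 kept their direction and side of the threshold, 968 weakened and 107 became stronger. Quantile normalization weakened 142 of 844, equal library medians 131, and the replicate block 3 of 586, while pseudocounts of 0.1 and 5 weakened 17 and 13. Undifferentiated germ cell medians kept their direction, and passed at the preset correlation of 0.01, under every setting, but with an estimated correlation the list passed in none of these comparisons (adjusted p = 0.0712 to 0.199). The medians had ranges over settings of 0.919 to 2.369 (young), 0.864 to 2.261 (tst mutant), 0.572 to 1.826 (tst RNAi), 0.414 to 1.647 (pelo) and 0.594 to 1.641 (hfp), from pseudocount 5 to 0.1. Leaving out 1 library gave medians of 1.697 to 1.725, 1.238 to 2.078, 1.032 to 1.349, 0.743 to 1.305 and 0.697 to 1.570 in the same order.

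Counts of called genes moved with the processing. For young wild type, with 983 genes, the count was 627 with a TPM of at least 5, where fewer genes are tested, 3322 with the replicate block, 2191 in a fit of the 2 groups alone and 324 to 384 without 1 library. For the tst mutant, with 375, it was 249 with a TPM of at least 5, 2082 with the block, 82 in the fit of 2 groups and 29 to 579 without 1 library. For tst RNAi, with 90, it was 56 with pseudocount 5, 46 with a TPM of at least 5, 26 with equal library medians, 429 with the block, 148 in the fit of 2 groups and 3 to 12 without 1 library. For pelo, with 20, it was 12 with a TPM of at least 5, 1 with equal library medians, 359 with the block, 0 in the fit of 2 groups, 55 with adult wild type as control and 3 to 34 without 1 library. For hfp, with 88, it was 875 with the block, 0 in the fit of 2 groups, 218 with adult wild type as control and 23 to 278 without 1 library. The pelo and hfp numbers are tied to no other label, though deviations of libraries with the same number correlated at 0.653 and 0.717 between heterozygote and mutant and at 0.171 to 0.38 between pelo and hfp groups. With the block 10 of 26 glutathione genes rose in pelo, and that list passed (adjusted p = 0.026 with an estimated correlation), while 16 muscle and 5 hemocyte genes rose and 4 chorion and 4 vitelline membrane genes fell. In hfp 17 muscle and 5 hemocyte genes rose and 8 maternal axis genes fell with it, and no list passed. The overlap of 9 genes became 4 with quantile normalization, 5 with equal library medians, 312 with the block and 2 to 65 without 1 library.

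Without 1 library the tst RNAi input count of 3427 was 1912 to 2588 and the pelo input count of 1044 was 500 to 1002. The control polysome count of 3572 was 1690 with quantile normalization and 1891 with equal library medians, and 3030 to 3597 without 1 preparation. The pelo ratio difference, with 0 genes, ranged from 0 to 1087 without 1 preparation. The tst RNAi ratio difference, with 1972, was 0 with quantile normalization, 54 with equal library medians, 1107 without the block and 0 to 3152 without 1 preparation. With pelo numbers crossed, chosen because pelo input and polysome deviations correlated at -0.449, the counts were 4106, 0 and 2861. Fewer libraries lower the power when 1 is left out, yet some of these counts rose, and the cause was not tested there or for the other moved counts. Sequencing depth is unknown, so its limits on weakly expressed genes cannot be stated.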

Other observations

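No test in this part was chosen after its own result was seen, though the patterns themselves were.

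Of the copies of ribosomal protein genes looked at, RpL22-like, RpS10a and RpS19b passed in at least 2 comparisons, with positive changes in all. No difference between copies or comparisons was tested. These genes belong to the undifferentiated germ cell list, which was drawn against the control inputs, so their calls in inputs are not independent evidence. RpL22-like, at 81.0 TPM in the bam RNAi input and 117 TPM in the bam mutant, was listed at 0 and 0.188 TPM in the control inputs, and rose in tst RNAi (3.33, SE 0.50) and pelo (3.31, SE 0.50), with a change of 0.37 (SE 0.50, adjusted p = 0.719) in young ovaries. RpS10a, at 251 TPM in the bam RNAi input against 1.54 and 2.69 TPM, rose in tst RNAi inputs (3.95, SE 0.61) and pelo inputs (3.92, SE 0.61). It passed in no total mRNA comparison (limma adjusted p = 0.068 to 0.964). RpS19b rose in young ovaries (3.03, SE 0.74) and both inputs, and passed in no other comparison. RpS5b, RpS14b, RpL24-like and RpL34a did not pass in any comparison. Reads of close copies may be shared, and these genes were chosen after their values were seen.

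Among undifferentiated germ cell list genes, 65 were not higher in young ovaries, and 15 of these rose in at least 1 mutant or RNAi group. CG31300 rose in the tst mutant (1.48, SE 0.29), tst RNAi (3.17, SE 0.29) and hfp (1.63, SE 0.29), the phosphatase gene Alp4 in the tst mutant (2.74, SE 0.64) and tst RNAi (3.35, SE 0.64), and CG13318 in the tst mutant (1.75, SE 0.40) and hfp (2.11, SE 0.40). Rpt6R (5.40, SE 0.51) and CG18628 (4.15, SE 0.97) rose in the tst mutant, Est-6 in tst RNAi (3.10, SE 0.65) and hog in hfp (5.40, SE 0.65).

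Genes beside tst were lower in the tst mutant as a median over the window, and a single copy of the region in flies with the deficiency fits. The median of the 20 tested genes around tst was -0.504, at percentile 0.51 of 1957 windows on the arm, while in tst RNAi it was at percentile 95.04. No single gene in the window passed as lower, and Lsd-1, the only one called, rose. At higher coordinates, from mbc to sba, all log2 fold changes but that of eIF4G2 (-0.15) were positive.

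Variants linked to the mutated gene might change nearby genes in pelo and hfp mutants. The share of called genes within 3 Mb was 1.80 times (Fisher p = 0.306) that of tested genes for pelo and 0.832 times (Fisher p = 1.00) for hfp, with 2 and 3 such genes, and in pelo inputs 62 of 996 called genes gave 1.06 times (Fisher p = 0.614), so linked variants could not be told apart from chance.

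The w transcript was near 0 in adult and young wild type although their labels list w+ marked transgenes, and ovaries without the marked UAS-Dcr-2 transgene fit. Dcr-2 in control input 1, with the same labelled genotype, was 2.538 log2 above the highest of the 4 wild type libraries and 3.559 above control input 2. In tst RNAi, labelled with UAS-Dcr2, Dcr-2 was at 37.3 and 61.6 TPM. Driver and Dcr-2 differences between the sets may thus add to the input comparisons. Since w was near 0 in adult wild type but not in tst RNAi, stock differences may also add to their total mRNA comparison. The stock used cannot be read from these values.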
